A study of Gallus gallus with 50 samples.

How the data were processed

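Single motor neurons of the spinal cord of chicken embryos at embryonic day 9 were profiled by SMART-seq2, a plate-style protocol that amplifies full-length cDNA from the poly(A) RNA of 1 cell. Per the labels, a fluorescent tracer was carried back along the axons from 1 of 2 muscles, written EMR and FDQ and not spelled out in the labels. The spinal cord was then dissociated with papain, and labelled cells were picked by hand into PCR strips. The muscle in the title of each sample set its group. There were 32 EMR cells and 18 FDQ cells, and each sample was 1 cell.

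The deposited table holds raw read counts of 20392 Ensembl gene IDs in 50 cells. The unit follows from the values, which are whole numbers with column sums that differ widely between cells. The submitters' processing notes name Trimmomatic 0.39, STAR 2.5.2, HTSeq 0.6.1 and the chicken build GRCg6a, without a role or order for any of them. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies are therefore uncertain. SMART-seq2 counts here are PCR reads without molecular identifiers, so intervals and floors cover counting error only. Intervals on shares of cells treat the cells as independent draws. No row of the table lacked a gene ID, every column matched 1 sample, and no columns were identical.

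The table gives gene IDs without gene names. The gene name table at hand follows another build, GRCg7b, and named 0 of the 20392 IDs. The 40 gene lists and cell type marker sets fixed before the data were examined, with 575 symbols, were therefore not analysed here. The same holds for chromosomes, mitochondrial genes, the sex of the embryos and motor neuron markers, so the identity of each cell rests on the labels. Genes are described by their Ensembl ID, and at most 2 IDs per direction are printed.

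The replicate of such an experiment is the embryo. The labels name no embryo, plate, strip or day for any cell, so each muscle counts as 1 sample. No test was made and no p-value is given. Cells with at least 50000 counts were kept (48 of 50), which left out the EMR cells E10 and E4. The counts of each gene were summed over the kept cells of a muscle, scaled to a total of 1000000 gene counts (CPM), and given with exact 95% Poisson intervals. The ratio of EMR to FDQ has an exact conditional interval from the Clopper-Pearson method. A group with no count took a floor of 3 counts over the group, which makes the ratio a bound. Gene IDs entered when at least 5 kept cells had a count, which left 12649. A total of 1195 IDs had no count in any cell.

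Shares of cells with a gene depend on depth, so each cell was thinned without replacement, with a fixed seed, to 200000 counts. That was the highest of 5 preset depths that kept at least 80% of the cells of each muscle. It kept 30 EMR and 16 FDQ cells and left out 2 cells of each muscle. A gene was detected in a cell with at least 1 count, and shares have exact Clopper-Pearson 95% intervals. Similarity between cells was Spearman's correlation over the 12649 IDs at that depth, across genes, which are not independent replicates. Cells were not clustered. No doublet caller was run, since the cells were picked singly by hand.

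The rule for named genes was written before the data were examined. It asked for a gene symbol and for a place outside the chromosomes Z and W and the mitochondrion, and neither condition could be applied here. Its leading part was otherwise used with its conditions and ranking as written. It ranks IDs by the difference in the share of cells at the thinned depth, among IDs detected in at least 40% of the cells of the higher group. These IDs need a ratio of at least 2 both in summed CPM and in the mean of per-cell CPM. They also need a ratio of at least 1.5 after leaving out, in each group, the cell with most counts of that ID. The first 2 IDs of each direction are given, fewer than the rule asked for. The other parts of the rule were not used here: 1 ranks abundant genes, and the others need gene names.

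The ratio was checked on counts simulated for 12640 gene IDs with the means and spread of the EMR cells and the real cell totals. For the comparison of EMR and FDQ, true log2 sizes of 1, 2 and 3 came back as medians of 0.97, 1.93 and 2.95 over 66, 72 and 62 changed IDs. These changed IDs were drawn only from IDs with mean expression above the median, so recovery of weaker IDs was not checked. Single IDs were recovered poorly, with quartiles of −0.04 and 1.73 for a true size of 1. The 12440 unchanged IDs had a median absolute log2 ratio of 0.85, with an upper quartile of 1.64. A further 20 draws had no difference between the muscles.

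The alternatives to the main settings were the mean of per-cell CPM, sums of thinned counts, edgeR's TMM scaling of the summed counts, DESeq2's size factors per cell and all 50 cells. Others were sums without the top cell, each cell left out in turn, other gene filters, detection at 5 counts, and counts as deposited without thinning. Alternatives with only cells of at least 5000 genes, with deposited counts in the cells of the fixed depth, and all those for similarity were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.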

Results

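Transcriptomes of single motor neurons were compared between cells that project to the muscle EMR and cells that project to the muscle FDQ, in chicken embryos at embryonic day 9. The title of the series places the question in the search for signatures of gene expression that belong to the target muscle. There were 32 EMR cells and 18 FDQ cells. The embryos behind the cells are not named in the labels, so each muscle was 1 sample without replicates. Each value below is a description of these cells, without a test. Intervals cover counting error only, of reads for sums and of cells taken as independent draws for shares, and leave out differences between embryos.

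The cells differed widely in depth. Total gene counts ranged from 36138 to 11014823 in EMR cells, with a median of 2561308. In FDQ cells they ranged from 61737 to 8245621, with a median of 4819862. After 2 EMR cells under 50000 counts were left out, the sums held 138554829 counts from 30 EMR cells and 76530951 counts from 18 FDQ cells. Cells with at least 5000000 counts gave 75.1% of the EMR sum and 78.8% of the FDQ sum, and therefore weigh most in the summed values.

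**Figure D1:**
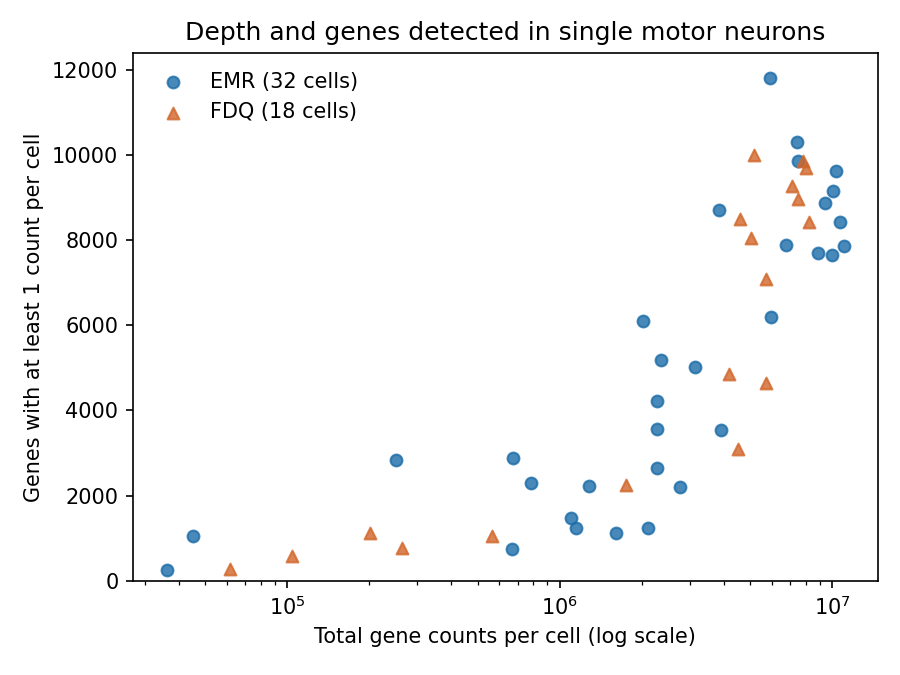
Each point is 1 cell, with its total gene counts on a log axis and the number of genes with at least 1 count on a linear axis; circles are the 32 EMR cells and triangles the 18 FDQ cells. Cells of both muscles spread from 244 to 11813 genes in EMR and from 273 to 9997 genes in FDQ.

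The number of genes detected per cell was the first property compared. In the counts as deposited, a median of 4611.5 genes had a count in all EMR cells (quartiles 2227 and 8021) and 5971 in all FDQ cells (quartiles 1397 and 8847.5). At 200000 counts in each cell, the median was 3523.5 genes in 30 EMR cells, with quartiles of 1656 and 6848.5 and a range of 616 to 9364. It was 6398 genes in 16 FDQ cells, with quartiles of 2268.25 and 7527.5 and a range of 708 to 8306. The ratio of the medians, EMR over FDQ, was 0.551 at equal depth. As deposited it was 0.673 in the same cells, a comparison added after seeing the data, and 0.854 over all kept cells, which include 2 shallow FDQ cells. The ranges overlapped. At least 5000 genes had a count in 16 of 32 EMR cells (50%, exact 95% interval 31.9% to 68.1%) and in 9 of 18 FDQ cells (50%, 26.0% to 74.0%).

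A small number of genes took much of the counts in some cells. The 10 most abundant genes of a cell held a median of 13.5% of its counts in EMR cells (range 7.68% to 89.9%) and 11.03% in FDQ cells (8.64% to 60.7%). They held over 50% of the counts in 6 of 32 EMR cells (18.8%, exact 95% interval 7.21% to 36.4%) and in 2 of 18 FDQ cells (11.1%, 1.38% to 34.7%).

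The gene IDs seen in the muscles were largely shared. A count in at least 1 kept cell was found for 17857 IDs in EMR and 16132 IDs in FDQ, and 14805 IDs had one in both. These numbers depend on the cells and counts summed, and EMR had more of both. At the fixed depth, 3310 IDs were detected in at least 50% of the EMR cells, 5163 IDs in at least 50% of the FDQ cells, and 3134 IDs in at least 50% of both. A core of 18 IDs was detected in 100% of the cells of both muscles. More IDs reached 50% of cells in FDQ, where the median cell at this depth also had more genes. Over the 12649 IDs that passed the filter, the share of cells, EMR minus FDQ, had a mean of −5.86 percentage points. The shares of single IDs below are given without a correction for that general shift.

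The main comparison set the summed expression of each gene in EMR cells against that in FDQ cells. Over 12649 gene IDs the log2 ratio of EMR to FDQ had a median of −0.05 and quartiles of −0.68 and 0.64. The median absolute log2 ratio was 0.66, and 64.2% of the IDs lay within 2-fold. With each cell given the same weight, through the mean of per-cell CPM, the median absolute log2 ratio was 0.93 and 52.3% of IDs lay within 2-fold. Spearman's correlation of the 2 kinds of ratio was 0.870 across genes, which are not independent replicates. Counts simulated without any difference between the muscles, with the spread between EMR cells and the real depths, gave a median absolute log2 ratio of 0.82 to 0.86 in 20 draws. These draws were wider than the data, and they took the spread of EMR cells for both muscles, so they do not show whether the ratios exceed the spread between cells.

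**Figure D2:**
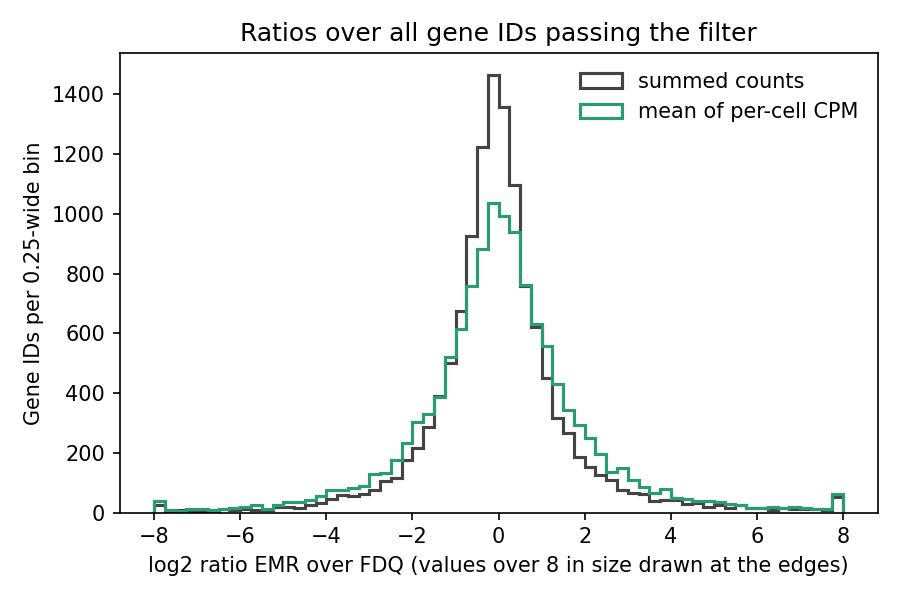
The histogram counts gene IDs by their log2 ratio of EMR to FDQ, for summed counts and for the mean of per-cell CPM, over the 12649 IDs that passed the filter. Both curves centre near 0 (medians −0.05 and 0.03), and the curve of equally weighted cells is the wider of the 2.

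Against this background, the rule fixed in advance picked the IDs with the largest differences in the share of cells among those that also met its conditions on the ratios. The files do not pair these IDs with gene names. ENSGALG00000029788 was detected at the fixed depth in 15 of 30 EMR cells (50%, exact 95% interval 31.3% to 68.7%) and in 2 of 16 FDQ cells (12.5%, 1.55% to 38.3%). Its summed expression was 280 CPM in EMR (exact Poisson 95% interval 277 to 283) and 8.17 CPM in FDQ (7.54 to 8.83), 34.3-fold higher in EMR (31.7 to 37.2, log2 ratio 5.10). The cell F24 held 83.0% of its FDQ counts, and without F24 the log2 ratio was 7.58. In the counts as deposited it was present in 16 of 30 EMR cells and 3 of 18 FDQ cells.

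ENSGALG00000007361 was detected at the fixed depth in 12 of 30 EMR cells (40%, 22.7% to 59.4%) and in 0 of 16 FDQ cells. The exact upper limit of the latter share is 20.6%, and 3 cells of 16 would be 18.8%. Summed over the kept cells it reached 50.4 CPM in EMR (49.2 to 51.6) and 0.327 CPM in FDQ (0.211 to 0.482). It was thus 154-fold higher in EMR (104 to 238, log2 ratio 7.27). The FDQ sum was 25 counts from 2 cells, F12 and F21. The log2 ratio was 8.004 without F12, 8.30 without F21 and 6.91 without E23, the cell with 26.0% of the EMR counts. As deposited, it had a count in 21 of 30 EMR cells and 2 of 18 FDQ cells.

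In the other direction, ENSGALG00000004376 was detected at the fixed depth in 11 of 16 FDQ cells (68.8%, 41.3% to 89.0%) and in 4 of 30 EMR cells (13.3%, 3.76% to 30.7%). Its summed expression was 64.3 CPM in FDQ (62.5 to 66.1) and 18.2 CPM in EMR (17.5 to 18.9), 3.54-fold higher in FDQ (3.37 to 3.72, log2 ratio −1.82). The log2 ratio was −2.47 without E11 and −2.50 without E17, the cell with 40.6% of its EMR counts. Without F8, the cell with 19.9% of its FDQ counts, the log2 ratio was −1.60. A count as deposited was present in 11 of 18 FDQ cells and 8 of 30 EMR cells.

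ENSGALG00000003944 was detected at the fixed depth in 9 of 16 FDQ cells (56.3%, 29.9% to 80.2%) and in 1 of 30 EMR cells (3.33%, 0.0844% to 17.2%). It reached 23.4 CPM in FDQ (22.3 to 24.5) and 1.72 CPM in EMR (1.51 to 1.96), 13.5-fold higher in FDQ (11.8 to 15.6, log2 ratio −3.76). The log2 ratio was −5.30 without E19, which held 68.2% of the EMR counts. It was −2.95 without F5, which held 47.4% of the FDQ counts. As deposited it had a count in 11 of 18 FDQ cells and 4 of 30 EMR cells.

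**Figure D3:**
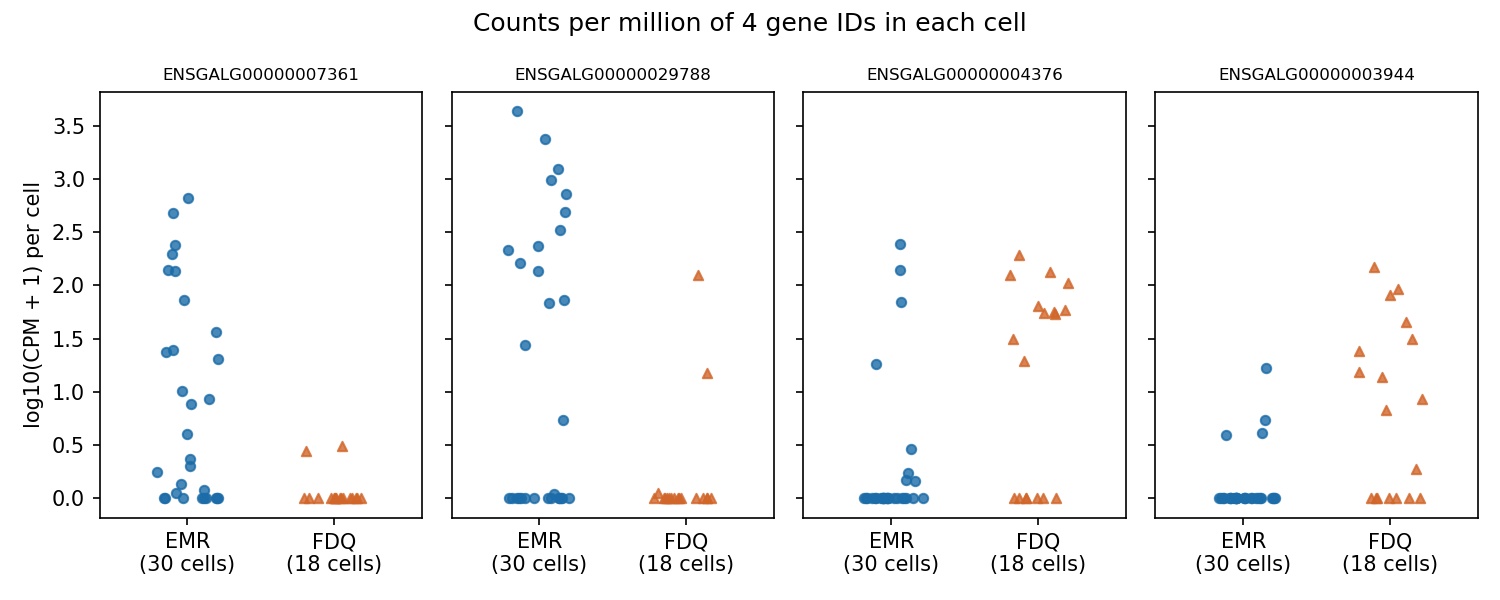
Each point is 1 kept cell, with its CPM of 1 gene ID as log10(CPM + 1), for 30 EMR cells (circles) and 18 FDQ cells (triangles), and points are spread sideways only for legibility. ENSGALG00000007361 and ENSGALG00000029788 reach higher values in EMR cells and ENSGALG00000003944 in FDQ cells, while ENSGALG00000004376 is present in more FDQ cells but reaches similar heights in a few EMR cells; each ID is at 0 in some cells of both muscles.

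None of these IDs was present in every cell of a muscle. Of the 30 EMR cells at the fixed depth, 5 had both EMR-higher IDs, 22 had at least 1 of them and 8 had neither. Of the 16 FDQ cells, 7 had both FDQ-higher IDs, 13 had at least 1 and 3 had neither. Among the cells with at least 5000 genes, a restriction added after seeing the data, ENSGALG00000029788 was detected in 12 of 16 EMR and 1 of 9 FDQ cells. ENSGALG00000007361 was detected in 7 of 16 EMR and 0 of 9 FDQ cells. ENSGALG00000004376 was detected in 4 of 16 EMR and 8 of 9 FDQ cells, and ENSGALG00000003944 in 1 of 16 EMR and 5 of 9 FDQ cells. Over all cells at the fixed depth, the differences in share, EMR minus FDQ, were 40 and 37.5 points for the EMR-higher IDs ENSGALG00000007361 and ENSGALG00000029788. They were −55.4 and −52.9 points for the FDQ-higher IDs ENSGALG00000004376 and ENSGALG00000003944. In the 20 simulated draws without a difference, the same rule gave a largest difference of 46.7 to 67.5 points toward EMR and 48.3 to 62.1 points toward FDQ. Each draw thus exceeded both EMR-higher IDs, and the FDQ-higher IDs lay within the simulated range. The draws varied each ID independently and had no general shift in detection between the muscles built in.

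Whole profiles were compared through the similarity of pairs of cells at the fixed depth. The median Spearman correlation across genes was 0.267 between EMR cells, 0.311 between FDQ cells and 0.273 between a cell of each muscle. In cells with at least 5000 genes it was 0.511, 0.662 and 0.595. Pairs of different muscles thus scored above pairs of EMR cells in the median. The correlations were higher in cells with more genes, and the median EMR cell had fewer genes at this depth. Detection and likeness of the cells cannot be told apart here. The most similar cell belonged to the same muscle for 27 of 30 EMR cells (90%, exact 95% interval 73.5% to 97.9%) and for 11 of 16 FDQ cells (68.8%, 41.3% to 89.0%). By group size alone these shares are 64.4% and 33.3%. A single cell can be nearest to several others, so these outcomes are not independent and the intervals do not measure their uncertainty. Under other settings the shares fell as low as 73.3% in EMR and 50% in FDQ. Among cells with at least 5000 genes, the shares were 14 of 16 EMR cells (87.5%) and 8 of 9 FDQ cells (88.9%), against 62.5% and 33.3% by group size. Embryo, strip and day are not in the labels, and cells of 1 muscle that shared any of these cannot be told from cells that shared only the muscle.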

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

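The alternatives with only cells of at least 5000 genes, with deposited counts in the cells of the fixed depth, and those for similarity were chosen after seeing the data. No alternative turned the direction of the 4 named IDs: all 36 values kept it. This is weak support, because the IDs were chosen for their direction in these same cells. The rule itself required it in the mean of per-cell CPM and in the sums without the top cells. Those values could not turn, and the other settings reuse mostly the same counts. Of 81 values under alternatives, 44 stayed within the interval or limit set around the main value and 37 moved beyond it. The log2 ratio ranged from 6.13 to 8.52 for ENSGALG00000007361, from 4.65 to 7.58 for ENSGALG00000029788, from −2.50 to −1.49 for ENSGALG00000004376 and from −5.85 to −2.83 for ENSGALG00000003944. The value 6.13 is a lower bound, as FDQ had no count of that ID after thinning. The value −5.85, also from thinned counts, rests on 3 EMR counts and has a counting interval of −8.15 to −4.25.

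The median absolute log2 ratio over genes, 0.66 in the main setting, was 1.05 with DESeq2's size factors, 1.004 for IDs with a count in at least 1 cell and 0.36 for IDs with a count in at least 25 cells. The last 2 changes follow from the genes tested. The cause of the first was not tested. DESeq2's factors also moved the median log2 ratio of all genes from −0.05 to 0.41. Relative to that shift the log2 ratios of the named IDs were 8.11, 6.27, −1.90 and −4.75, in the order above. Detection at 5 counts lowered the median of genes per cell alike in both muscles, from 3523.5 to 2523.5 in EMR and from 6398 to 4583 in FDQ, and left the ratio at 0.551. The ratio of medians, EMR over FDQ, was 0.551 at equal depth, 0.673 in the deposited counts of the same cells and 0.854 in the deposited counts of all kept cells, so that both depth and the 2 shallow FDQ cells moved it. It ranged from 0.515 to 0.592 with each cell left out in turn, a range that does not measure the spread between cells. The share of EMR cells nearest to an EMR cell was 73.3% for IDs with a count in at least 25 cells, against 90% in the main setting and 64.4% by group size. With Pearson's correlation of log2(CPM + 1) on deposited counts, the share of FDQ cells nearest to an FDQ cell was 50%. It was 68.8% in the main setting and 33.3% by group size. The cause was not tested in either case.

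Alternatives that need gene names or chromosomes were not run: scaling without mitochondrial genes, cell filters by motor neuron or other markers, and all settings of the gene lists. No paired analysis was possible because the numbers name cells and no test was made. At 200000 counts, 1 count is 5 CPM, which limits the detection of weaker genes in a cell. The number of cells limits the shares: a gene seen in none of 16 FDQ cells has an exact upper limit of 20.6%.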

Other observations

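The tests of depth, abundant genes and muscle below, and those against the number of genes detected, were chosen only after the results were seen. The test of the share of the block in held-out cells and the simulation were set before their results were seen, and the measure by percent of counts after.

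A block of genes was on together in some cells and off in others. It was sought in the 20 cells with at least 7500 genes, where a gene was on at 5 CPM or more and had to be on in at least 5 cells and off in at least 5. The most common on-off pattern was shared by 8 gene IDs, against 4 for the next most common. With IDs that differed from it in at most 1 cell, the block held 10 IDs, none of them among the 4 named above. At 1 CPM or more, 13 of the 20 cells had at least 90% of the block and the other 7 had at most 30%. The block took 0.199% to 0.279% of the counts of each of the 13 cells and at most 0.00156% in the other 7. The IDs were chosen for this pattern in the same 20 cells, so these splits are no separate support for it. How many IDs would share a pattern without any link between them was not estimated.

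The number of genes detected does not account for the block: 5 of the 7 cells without it had more genes than the median of 8715 in the cells with it. Muscle does not account for it either, since the block was on in 8 and off in 4 EMR cells, on in 5 and off in 3 FDQ cells, so that every combination had at least 3 cells. A candidate explanation is a trait of the embryo, such as its sex, that makes genes all present or all absent in each of its cells. In 13 cells with at least 2000 but under 5000 genes, which did not define the block, 7 had at most 10% of it, 5 had at least 40%, and 1 (7.69%) lay between, where the hypothesis allowed up to 20%. This limit decides nothing: with 10 IDs, evenly spread shares would put 18.2% between, 4 of the 13 cells lay exactly at 10% or 40%, and by percent of counts 4 of the 13 (30.8%) lay between the 2 sets of defining cells. Of 5 further cells with at least 5000 but under 7500 genes, 4 had at most 10% of the block and 1 had at least 40%, though by percent of counts 1 of the 5 lay between. The hypothesis stays open, as does a state of single cells, since embryo and chromosome were not analysed here.

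Genes detected per cell spanned a wide range. Depth alone does not account for it, because at 200000 counts the highest cell still had 15.2 times the genes of the lowest. Abundant genes that take up the counts do not account for it either: without the 10 most abundant IDs, the ratio was 12.97 in the 44 cells that kept 200000 counts. This left out E12 and F11, in which abundant genes held most counts, and the shallow cells F13 and F20. At 50000 counts, a depth added after the result was seen, 47 cells remained, E12 and F11 among them. There the ratio was 14.4, with the shallow cell F20, not E12 or F11, as the lowest. The 90th percentile of cells had 7.28 times the genes of the 10th, a value not calculated with the 10 IDs kept. Loss of RNA in picking or amplification and differences in the RNA content of the cells stay open and untested, and no biological explanation was tested.

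The differences in share of the 4 named IDs were weighed against the number of genes detected and against variation between cells. The lower median of genes in EMR cells at equal depth could bear on the FDQ-higher IDs, ENSGALG00000004376 and ENSGALG00000003944. Among cells with at least 5000 genes their differences were 1.15 and 0.932 times those over all cells, so they changed little. With 16 EMR and 9 FDQ cells the exact intervals of the shares overlapped, which is not a test of a difference. For ENSGALG00000004376 the EMR interval ended at 52.4% and the FDQ interval began at 51.8%. The limit of 5000 genes also does not make the number of genes equal between the muscles. This explanation therefore stays open. Variation between cells was not excluded for any of the 4. In draws without a true difference, the largest difference was 46.7 to 67.5 points toward EMR and 48.3 to 62.1 points toward FDQ. The EMR-higher IDs (40 and 37.5 points) lay below these ranges. The FDQ-higher IDs (−55.4 and −52.9 points, EMR minus FDQ) lay within them. The draws cannot show that this variation is the cause. In them each ID varied independently of the others, and both muscles took the means and spread of EMR cells. They therefore had no general shift in detection between the muscles built in, and no variation common to many IDs of a cell. The draws' differences in share spread about their median as in the data (median 6.67 to 7.92 points against 7.92, a check added after the result was seen), with a slightly wider 95th percentile (25.4 to 26.7 against 23.8). Their log2 ratios were wider than the data (median absolute 0.82 to 0.86 against 0.66), which can change how many IDs meet the rule. Without its conditions on ratios, a comparison also added later, the largest differences in the data, 48.3 points toward EMR and 55.4 toward FDQ, lay within the draws' 47.5 to 67.5 and 50 to 62.1 points. Muscle and differences between embryos stay open too, and they cannot be told apart without embryo labels.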
